A study of Mus musculus with 51 samples.

How the data were processed

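The samples were 51 spotted 2-colour arrays hybridised with RNA of CRL1606, a mouse B-cell hybridoma line that secretes an antibody against fibronectin. Per the labels, both channels of an array held the same hybridoma RNA, with 100 genes spiked into channel 1 and another 100 into channel 2 at one amount per gene. The amounts were 0, 0.05, 0.1, 0.25, 0.5 and 0.75 pmol on 6 arrays each, and 0.025, 0.15, 0.2, 1 and 2 pmol on 3 arrays each. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between arrays, which may be technical.

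The authors deposited 1 log2 ratio per spot and array, and the scanner intensities were not analysed here. The log base was not stated and was read from the values, which include log2 of small whole-number ratios. How the authors subtracted background, filtered spots or normalised the deposited log2 ratios is not given in the sources used here, nor is the channel in the numerator. A ratio is therefore called positive or negative, with no statement of which channel was brighter. The array medians of the deposited values ran from -3.33 to 0.951, with a median of -1.34, so the arrays had not been centred. A value of 16.61, which is log2 of a ratio of 100000, occurred 1074 times as an upper limit and was treated as missing.

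The 16896 spots form 48 print blocks of 352 spots in rows of 22. Each probe was printed in a pair of spots 22 positions apart: 5458 pairs carried the same sequence accession listed for the platform, 0 carried different ones, 1 pair had an unlisted member and 2989 pairs were unlisted. The pair was averaged, giving 8448 probes. The 11 block positions that held no named gene in any block (9 positions) or one gene in every block (Gapdh and Pdia3) were taken as controls, and their 528 probes were left out. The remaining 7920 probes are the features of the text. The averaging and the control rule were set after the layout had been seen. Of these features, 5347 had 1 gene symbol and 2573 had none or several in the platform annotation. Symbols were updated through Entrez identifiers with the RefSeq genes of assembly GRCm38.p6, used for names only (10766 of 16896 spots matched). A feature without a symbol is given by the number of its first spot.

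Each array was centred on the median log2 ratio of its non-control spots. Features were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the package data.table for reading: 1 fit of all 51 arrays with 1 mean per amount, empirical Bayes moderation and two-sided tests, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. At least 2 measured arrays per group were needed. Every amount was set against the 6 arrays at 0 pmol, so the 10 comparisons share those arrays and their counts are not independent. The 0 pmol mean was also tested against 0, and a slope on log2 of the amount was tested over the 45 spiked arrays, for features measured on at least 10. For the rankings, each amount and the 6 arrays at 0 pmol were fitted on their own, with and without moderation. A difference is on the log2 scale throughout.

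The spiked genes are not named in the sources used here. A candidate set was therefore defined before the data were examined: the 100 highest and the 100 lowest mean ratios on the 3 arrays at 2 pmol, among features off 0 there with the same sign on each measured array. The means and signs came from the 2 pmol arrays alone. The test against 0 took its spread from the fit of all arrays, those at 0 pmol included, so the choice was not fully independent of them. For each array, the candidate separation is the median of the positive candidates minus that of the negative ones, divided by 2. Arrays at 2 pmol were left out of the slope of the separation. Groups of arrays were compared with exact two-sided permutation tests. Correlations were tested with 100000 permutations, or with all orders where there were fewer than 10 arrays. The rule for named genes was also fixed beforehand. At 2 pmol it takes the 12 highest and 12 lowest differences past the threshold with the same sign on every measured array, and at each other amount the 2 highest and 2 lowest. For the 0 pmol mean and the slope it takes 3 each way, and for each gene list up to 4 called members. At most 2 features without a symbol are named each way. The 8 gene lists were written beforehand and tested with camera, at a preset correlation of 0.01 and at an estimated one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

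Whether the spiked arrays ran the same way was checked over the candidates: the lowest correlation of any of the 42 arrays of 0.025 to 1 pmol with the 2 pmol mean was 0.788, so no sign was turned. The 6 arrays at 0 pmol carry no spike and could not be checked in this way, so their orientation is taken to be the same. Over all features, the lowest correlation between any pair of the 51 arrays was -0.143. The largest share of identical values between any pair of arrays was 1.06%, so no array was a copy of another.

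Arrays fell into sets that the labels do not name. They were found by Ward clustering of the arrays on 5689 features whose mean over the spiked groups lay within 0.5 of the 0 pmol mean, outside the candidates, and 8 sets were kept. Set A held 12 arrays: 0 pmol replicates 4 to 6, 0.1 pmol replicates 4 to 6, 0.75 pmol replicates 1 to 3, and 3 arrays at 0.25 and 0.5 pmol. The 0 pmol replicates 1 to 3 formed a set of their own. Sets B and C held 8 spiked arrays each, over 3 and 5 amounts. Set D held the 3 arrays at 2 pmol with 1 at 0.25 and 2 at 0.5 pmol. Set G held the 3 arrays at 1 pmol and 0.75 pmol replicate 4. With set as a covariate, amounts with no array in set A are thus compared with 0 pmol only through arrays of other amounts. The sets were defined after seeing the data, and the choice among clusterings was made then too. Average linkage with 6 sets was used first, and it left 36 arrays, all of 0 pmol among them, in 1 set. Ward clusterings with 4 to 8 sets were then looked at and the one with 8 was kept, so counts with array set as a covariate are given for the other clusterings as well.

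The number of arrays limits the precision. On simulated data with the real means, spreads and missing values, 7920 features and 50 changed features of each size, the comparison of 2 pmol (3 arrays) with 0 pmol recovered 90% of changes of 2 and 24% of changes of 1 on the log2 scale. That of 0.5 pmol (6 arrays) recovered 90% and 56%. The slope test recovered 92% of slopes of 0.25 per doubling. False calls made up 6.03%, 4.58% and 5.66% of the calls in these 3 simulations, and between 2.97% at 0.15 pmol and 10.1% at 0.1 pmol over the comparisons of all 10 amounts. The simulated noise was independent between features and arrays and held no array sets, so these shares do not give the false calls of the real data. There, 0 pmol replicates 4 to 6 against 1 to 3, with no spike in either, called 470 features.

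Alternatives fixed before the data were examined were the uncentred values, arrays scaled to one median absolute deviation, features measured on all 51 arrays, robust moderation, stricter thresholds, other sets of arrays in the fit, replicates left out 1 at a time, a replicate block, and other definitions of the candidates. Alternatives added after seeing the data were control positions kept, capped values kept, each print block centred, each spot as its own feature, array set as a covariate under each clustering, comparisons within a set, and arrays of doubtful quality left out.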

Results

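The data comprised 51 arrays in 11 groups of spiked amount, from 0 to 2 pmol per gene. The series is titled as an evaluation of methods that identify changed genes, with RNA spiked in at known amounts. The arrays measured between 8376 and 16869 of the 16896 spots, with a median of 16715. The 3 arrays at 1 pmol missed from 13.5% to 50.4% of their spots, and all others from 0.16% to 9.22%. The paired spots of a probe correlated across features with a median r of 0.882 over the arrays. The lowest value, 0.20, was that of 0.75 pmol replicate 4.

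The comparison of 2 pmol with 0 pmol asked which features carried the largest spike. On the positive side, Galnt13, an enzyme that starts mucin-type O-glycosylation, had the largest difference. Its log2 ratio was 9.76 ± 0.53 (SD, n = 3) at 2 pmol and -0.62 ± 0.53 (SD, n = 5) at 0 pmol, a difference of 10.38 with a standard error of 0.65. It was followed by Cald1, the actin-binding caldesmon (8.61), Zfp292, a zinc finger protein (8.47), and Tlr1, a receptor for bacterial lipopeptides (8.46). Sspn, a member of the dystrophin complex (8.36), Slc2a5, the fructose transporter (7.83), and Cpsf6, a subunit of the mRNA cleavage factor (7.61), came next. Atp2b2, a plasma membrane calcium pump (7.59), the transcription factor E2f4 (7.27) and the trophoblast glycoprotein Tpbg (7.19) completed the named positive genes. A pair of features with no symbol, spots 839 (8.44) and 8362 (8.37), lay among them. All 12 had a positive log2 ratio on every spiked array that measured them.

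On the negative side, Zfp330, a zinc finger protein, had the largest difference, -7.29 with a standard error of 0.73. Its log2 ratio was -7.10 ± 0.20 (SD, n = 3) at 2 pmol and 0.19 ± 0.11 (SD, n = 6) at 0 pmol. The catalytic subunit of protein kinase A, Prkaca, differed by -7.25, and the poly(A) polymerase Papola by -6.98. Both probes of Fem1c, a substrate receptor of a ubiquitin ligase, were in the list, with differences of -7.24 at spot 15721 and -6.90 at spot 2642. The glucocorticoid receptor Nr3c1 (-6.93), the replication checkpoint protein Topbp1 (-6.82) and the T-cell receptor alpha gene Tcra (-6.54) followed. Sox11, a transcription factor (-6.45), Nfe2l1, a stress-responsive transcription factor (-6.39), Ms4a4b, a membrane protein of lymphocytes (-6.20), and the feature without a symbol at spot 13160 (-6.65) completed the list. Of these 12 features, 9 had a negative log2 ratio on every spiked array that measured them; Tcra had one on 41 of 45, Nfe2l1 on 44 of 45 and the Fem1c probe at spot 2642 on 42 of 43. Adjusted p in limma was at most 6.09e-06 among the 24 features. With array sets from a Ward clustering with 6 sets as a covariate, that probe of Fem1c no longer passed at 2 pmol (-4.36, limma adjusted p 0.0577).

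**Figure D1:**
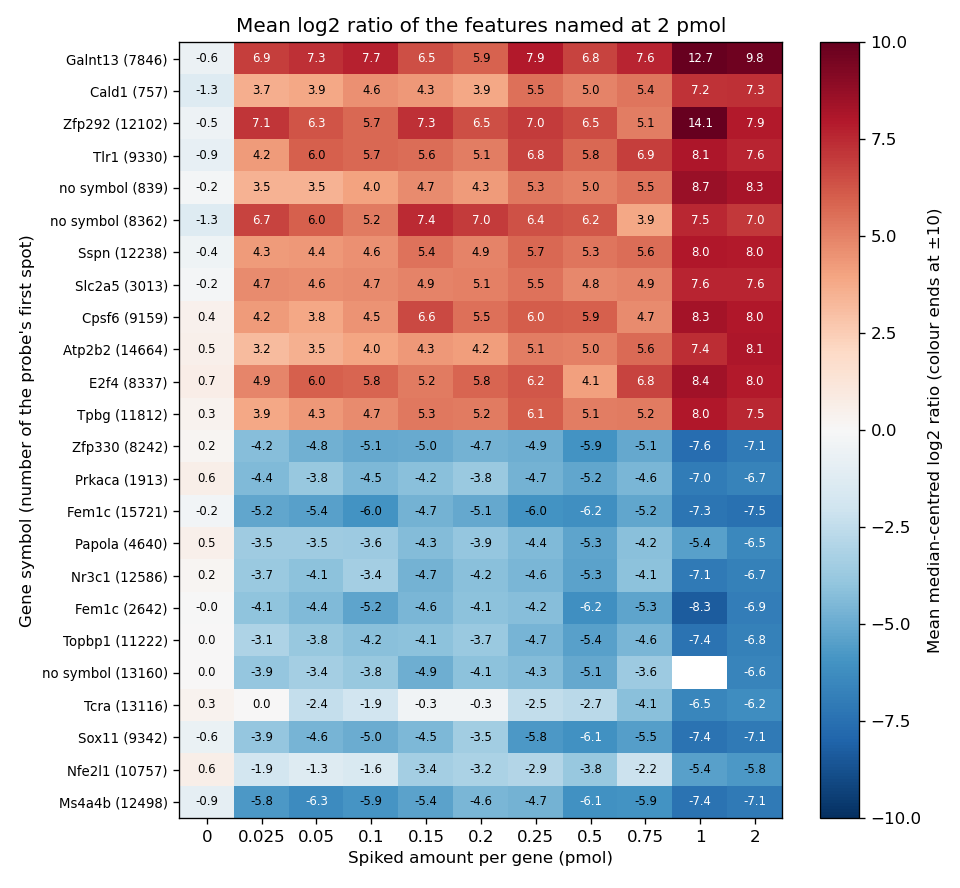
Mean median-centred log2 ratio (colour and printed value) of the 24 features named at 2 pmol (rows, gene symbol and first spot number) at each spiked amount in pmol (columns); a blank cell was measured on no array. Galnt13 goes from -0.62 at 0 pmol to 9.76 at 2 pmol and Zfp330 from 0.19 to -7.10, while Tcra lies at 0.01 at 0.025 pmol and -6.21 at 2 pmol.

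In all, 1239 of 7917 features tested differed between 2 and 0 pmol, 817 with a positive and 422 with a negative difference. Of these, 247 were at least 2 log2 units (4-fold) positive and 145 as far negative. Among the 200 candidates, 197 were called, as their choice on these 2 pmol arrays largely fixes, and 1042 of the called features were not candidates. These others had a median absolute difference of 1.27. Without 2 pmol replicate 3 the count was 763, and with array set as a covariate, an alternative added after seeing the data, it was 418. That drop depended on how the sets were drawn: it was 1477 with the sets of an average-linkage clustering and between 370 and 471 with the other Ward clusterings. With the 8 sets, no 0 pmol array shared a set with 2 pmol, so the 418 was reached through 1 array at 0.25 and 2 at 0.5 pmol. Without centring, 2782 were positive and 81 negative.

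The 8 gene lists, which were chosen for a hybridoma and not for the spike, held few measured genes. In the cell cycle list, 4 of 11 probes passed the test. The mitotic kinesin Kif11 was positive (1.78), and the replicative helicase subunit Mcm7 (-1.10), the mitotic kinase Plk1 (-0.96) and cyclin D1, Ccnd1 (-0.88), were negative. The difference of Plk1 came mostly from its mean at 0 pmol (0.90, against -0.06 at 2 pmol). Mcm7 lay at 0.59 at 0 pmol and -0.51 at 2 pmol, while Kif11 and Ccnd1 lay farther from 0 at 2 pmol. In the glycolysis list, 3 of 13 probes passed. They were both probes of the candidate Hk2, the hexokinase, which went opposite ways (3.79 and -3.11), and the phosphofructokinase Pfkm (-1.30). The respiratory chain subunit Ndufa2, a candidate (-4.70), was called among the 4 probes of the oxidative phosphorylation list, and the B-cell coactivator Pou2af1 (-1.68) among the 3 immunoglobulin and plasma cell probes.

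Of 17 probes for markers of liver, muscle, nerve and stroma, 4 were called, all positive. They were the keratin Krt18 (4.25, a candidate), the collagen Col1a2 (1.12), the GABA-synthesising enzyme Gad1 (1.09) and the synaptic vesicle protein Syt1 (1.03). Among 6 probes for T cells, NK cells and myeloid cells, Cd3e, part of the T-cell receptor complex (2.02), was positive and the costimulatory receptor Cd28 (-0.68) negative. Some of these differences came mostly from the 0 pmol arrays. The means at 0 and 2 pmol were -1.63 and 0.39 for Cd3e, -0.90 and 0.22 for Col1a2, and -0.76 and 0.27 for Syt1. Krt18, Gad1 and Cd28 lay farther from 0 at 2 pmol. In limma, 0 of 7 probes for ER folding and secretion and 0 of 4 for cytosolic ribosomal proteins passed, with 2 and 0 at an unadjusted p under 0.05. Adjusted over the list alone, the counts were the same except for oxidative phosphorylation, with 2. In the camera tests 0 of 16 passed, over both the 2 pmol comparison and the 0 pmol means, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.102. With an estimated correlation 0 of 16 passed too, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.546. At 2 pmol the T-cell list had a positive median (0.15) and mean (0.29) with a negative camera direction, and the immunoglobulin list a positive median (0.23) with a negative mean (-0.36) and direction.

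At the lower amounts, the comparisons asked how much of a spike was needed for a feature to be told from 0 pmol. Galnt13 was among the 2 most positive features at 0.05, 0.1, 0.25, 0.5 and 0.75 pmol, with differences of 7.89, 8.29, 8.57, 7.38 and 8.26. Zfp292 was so at 0.025, 0.15 and 0.2 pmol (7.67, 7.84 and 7.02), and Tlr1 at 0.1, 0.75 and 1 pmol (6.60, 7.74 and 8.95). The feature at spot 8362 was so at 6 of these amounts, with 8.06 at 0.025 pmol and 7.55 at 0.5 pmol. The value of Zfp292 at 1 pmol, 14.65, rested on 2 arrays with an SD of 2.76. At 0.025 pmol, the difference of Zfp292 was 4.16 with array set as a covariate, with a limma adjusted p of 0.0947.

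On the negative side, the tyrosine kinase Tec led at 0.025 and 0.05 pmol (-5.19 and -5.73), with Prkaca (-5.00) and Ms4a4b (-5.45) behind it. With the arrays scaled to one spread, Tec at 0.025 pmol no longer passed (-4.07, limma adjusted p 0.0744). At 0.1 pmol the Fem1c probe at spot 15721 (-5.74) and the N-acetylglucosamine kinase Nagk (-5.55) were lowest. At 0.15, 0.2 and 0.25 pmol the scaffold protein Iqgap2 was listed with -5.07, -5.05 and -5.63, beside Zfp330 (-5.20 and -4.88) and then the same Fem1c probe (-5.72). Zfp330 and the other Fem1c probe, at spot 2642, were lowest at 0.5 pmol (-6.13 and -6.12) and 0.75 pmol (-5.30 and -5.27), and Nr3c1 (-7.30, 2 arrays) at 1 pmol, followed by the feature at spot 7315 (-7.15, 2 arrays), which was not a candidate.

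The counts of called features did not follow the amount in order. They were 394 at 0.025 pmol, 329 at 0.05, 496 at 0.1, 845 at 0.15, 704 at 0.2, 1031 at 0.25, 1987 at 0.5, 593 at 0.75 and 2562 of 6030 tested at 1 pmol. Positive and negative calls numbered 132 and 262 at 0.025 pmol, 178 and 151 at 0.05, 324 and 172 at 0.1, 537 and 308 at 0.15, and 477 and 227 at 0.2. They numbered 711 and 320 at 0.25 pmol, 1115 and 872 at 0.5, 390 and 203 at 0.75, and 956 and 1606 at 1 pmol. Without centring the balance moved by over 10 percentage points at all amounts but 0.05 pmol. The counts were then 94 and 42 at 0.025 pmol, 162 and 49 at 0.1, 334 and 56 at 0.15, 92 and 89 at 0.2, and 423 and 65 at 0.25. At 0.5, 0.75 and 1 pmol they were 7171 and 60, 94 and 76, and 285 and 286. With centring, the balance at 0.025 pmol turned over features measured on all 51 arrays (106 and 84). It also turned with array set as a covariate (26 and 22). Without 0.025 pmol replicate 2 it was near even, with 48.5% positive, and without replicate 1 or 3 it stayed mostly negative.

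Other settings moved some counts by over 1.5 times. With the arrays scaled to one spread they were 74 at 0.025 pmol, 186 at 0.05 and 1300 at 1 pmol. Against 0 in place of the 0 pmol arrays they were 1843 at 0.025 pmol, 2167 at 0.05 and 1067 at 0.75 pmol. Over features measured on all 51 arrays they were 190 at 0.025 pmol, 319 at 0.1, 1155 at 0.5 and 1623 at 1 pmol. With replicates 1 to 3 they were 698 at 0.025 pmol, 684 at 0.25 and 963 at 0.5, and with replicates 4 to 6 they were 1003 at 0.05 pmol, 272 at 0.1 and 967 at 0.75. Leaving out single arrays did so too: without 0.025 pmol replicate 3 there were 204 calls, without 0.1 pmol replicate 2 there were 321, without 0.15 pmol replicate 2 or 3 there were 426 or 381, and without 0.2 pmol replicate 2 or 3 there were 359 or 456. Within the set of arrays that holds 0 pmol replicates 4 to 6, 810 features were called at 0.1 pmol, 620 at 0.25 pmol and 763 at 0.75 pmol. With array set as a covariate over all arrays, the counts were 48, 137, 1042, 358, 359, 703, 659, 763 and 1480 from 0.025 to 1 pmol. The 1480 rests on 0.75 pmol replicate 4, the array whose paired spots agreed least and the only array of another amount in the set of the 1 pmol arrays. With the average-linkage sets the counts were 513, 383, 412, 1084, 937, 1048, 1720 and 609 from 0.025 to 0.75 pmol, and 1 pmol could not be told from its set.

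**Figure D2:**
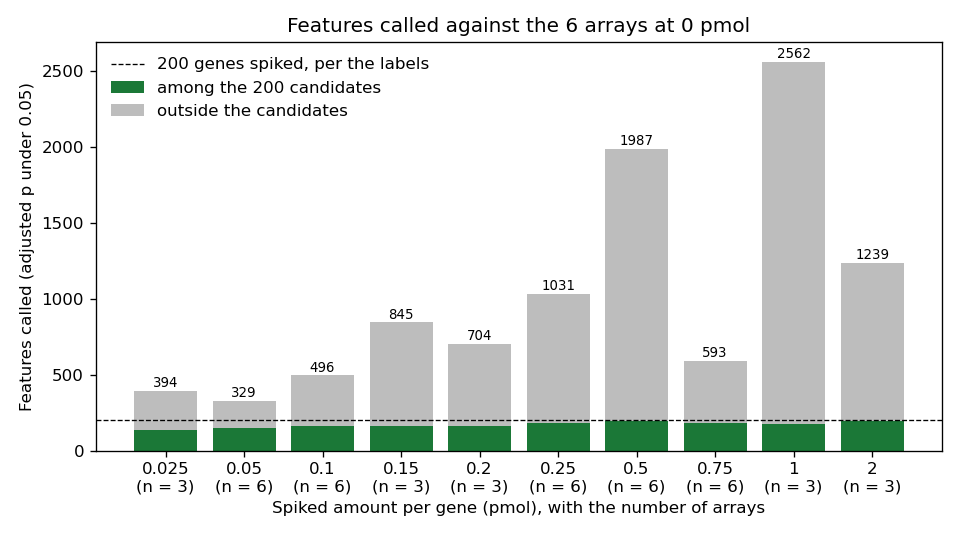
Number of features with a limma adjusted p under 0.05 against the 6 arrays at 0 pmol (bars, printed totals) at each spiked amount in pmol, split into candidates (green) and other features (grey); the dashed line is the 200 genes spiked per array, per the labels. Calls among the candidates lie between 134 at 0.025 pmol and 197 at 2 pmol, and the total exceeds 200 at each amount.

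The candidates show how the called share of likely spiked features moved with the amount. Of the 100 positive candidates, 78 had a positive log2 ratio on every array of 0.025 to 1 pmol that measured them, and 45 of the 100 negative candidates had a negative one. Called candidates with the expected sign numbered 134 of 200 at 0.025 pmol, 148 at 0.05, 159 at 0.1, 165 at 0.15, 161 at 0.2, 184 at 0.25, 194 at 0.5 and 183 at 0.75. At 1 pmol, 175 of the 180 candidates tested were called. The groups of 3 and of 6 arrays differ in power, so these counts are not a curve of detection by amount alone. Called features outside the candidates numbered 260, 181, 337, 680, 543, 847, 1793, 410 and 2387 from 0.025 to 1 pmol.

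The candidate separation at 0 pmol was 0.04 ± 0.03 log2 units (SD, n = 6). It was 2.71 ± 0.45 (n = 3) at 0.025 pmol, 2.60 ± 0.82 (n = 6) at 0.05, 2.57 ± 0.86 (n = 6) at 0.1, 3.53 ± 0.20 (n = 3) at 0.15 and 3.43 ± 0.35 (n = 3) at 0.2. It was 3.41 ± 0.59 (n = 6) at 0.25 pmol, 3.62 ± 0.29 (n = 6) at 0.5, 2.77 ± 1.04 (n = 6) at 0.75 and 4.82 ± 0.17 (n = 3) at 1 pmol. All 9 groups lay apart from the 0 pmol arrays. The exact permutation p was 0.0119 for groups of 3 and 0.00216 for groups of 6, the smallest these designs allow, and 0.0119 and 0.0039 after Benjamini-Hochberg adjustment. The 2 pmol arrays, which chose the candidates, gave 4.77 ± 0.17 (n = 3).

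**Figure D3:**
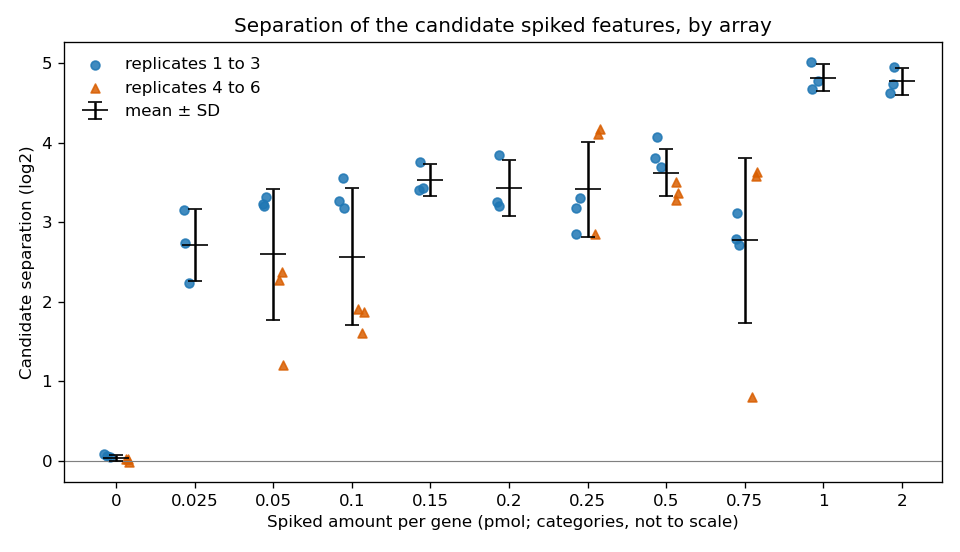
Candidate separation in log2 units for each of the 51 arrays (points, circles for replicates 1 to 3 and triangles for replicates 4 to 6) by spiked amount in pmol, with the group mean and SD (black); amounts are evenly spaced categories. The arrays at 0 pmol lie between -0.02 and 0.08, 0.75 pmol replicate 4 lies at 0.81, and the arrays at 1 pmol lie between 4.67 and 5.01.

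Over the 42 arrays of 0.025 to 1 pmol, the separation rose by 0.24 log2 units per doubling of the amount (standard error 0.08, 95% interval 0.08 to 0.39). Pearson's r was 0.434 (permutation p = 0.00382, adjusted p 0.0102 over 8 relations) and Spearman's rho 0.473 (permutation p = 0.00168, adjusted p 0.00672). The arrays were permuted singly, and the interval takes them as independent. Arrays of 1 amount often share an array set, so these p-values may be too small and the intervals too narrow. Without the 3 arrays at 0.025 pmol, the amount farthest from the median, r was 0.426. Without the 3 arrays at 1 pmol the slope was 0.14, with r 0.285 (permutation p = 0.0785, adjusted p 0.0897) and rho 0.340 (permutation p = 0.0347, adjusted p 0.0555), so neither passed after adjustment without those arrays. With the arrays scaled to one spread the slope was 0.19 and r no longer passed (permutation p = 0.11). Without 0.75 pmol replicate 4 the slope was 0.29, and without both that array and the 1 pmol arrays it was 0.21 and r passed (permutation p = 0.00362), so the loss without the 1 pmol arrays depended on that array. Within array sets, the slope was 0.42 in set A (9 spiked arrays), 0.37 in set B (8 arrays) and 0.02 in set C (8 arrays). The exact permutation p of Pearson's r was 0.0236, 0.0214 and 0.927 in these sets, and that of Spearman's rho 0.127, 0.00714 and 0.711 (adjusted 0.0315, 0.0315 and 0.927 for r, and 0.145, 0.0158 and 0.711 for rho), so set A passed by r and not by rho. With set as a term over all 42 arrays it was 0.38 (95% interval 0.17 to 0.60), and with the other clusterings it lay between 0.17 and 0.40.

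Replicates of one amount did not always agree. At 0.1 pmol, the mean separation was 3.34 in replicates 1 to 3 and 1.79 in replicates 4 to 6, and at 0.05 pmol it was 3.25 and 1.95. At 0.5 pmol it was 3.86 and 3.39, at 0.75 pmol 2.87 and 2.67, and at 0.25 pmol, with the opposite order, 3.11 and 3.71. The exact permutation p was 0.1 at 0.05, 0.1 and 0.5 pmol, the smallest that 3 arrays against 3 allow, 0.4 at 0.25 pmol and 1 at 0.75 pmol, so none of the 5 comparisons could pass the threshold. Replicates 4 to 6 at 0.1 pmol lay in another array set than replicates 1 to 3, as they did at 0.05 pmol. Their paired spots also agreed less, with r of 0.477, 0.495 and 0.578 at 0.1 pmol and 0.484, 0.444 and 0.675 at 0.05 pmol. In replicates 1 to 3 of these amounts r lay between 0.930 and 0.961. Array set and spot agreement cannot be told apart here.

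The slope of each feature on the amount was tested over the 45 spiked arrays. The steepest positive slopes were those of Ino80, the ATPase of a chromatin remodelling complex (0.85 ± 0.14 SE per doubling), the translesion DNA polymerase Polh (0.83 ± 0.11 SE) and the feature without a symbol at spot 9467 (0.76 ± 0.10 SE). The steepest negative ones were those of Tcra (-0.82 ± 0.16 SE), Sft2d1, a vesicle transport protein (-0.61 ± 0.09 SE), and the aspartic protease cathepsin E, Ctse (-0.60 ± 0.10 SE). All 6 were candidates and had a limma adjusted p of at most 0.000183. Most were printed directly next to other candidates of the same sign. Ino80 lay beside Cpsf6, Polh above spot 9467, Ctse between Ms4a4b and Nr3c1 in a column, and Tcra above spot 13160. Whether position played a part in these slopes was not tested. In all, 1833 of 7920 features had a slope past the threshold, 1030 positive and 803 negative, and 1705 of them were not candidates. The candidates were chosen on the 2 pmol arrays, which partly fixes the sign of their slopes, so these were fitted again without those arrays. Then 55 of 100 positive candidates had a positive slope past the threshold and 44 of 100 negative ones a negative slope, with median slopes of 0.28 and -0.21. With array set as a term 183 features passed, 104 of them outside the candidates, and the slope of Tcra no longer passed (-0.42, limma adjusted p 0.0839). That count depended on the clustering, with 1744 under average linkage and between 183 and 1069 under the other Ward clusterings. Without the 0.025 pmol arrays 970 features passed, over features measured on all 51 arrays 1158, with the amount in pmol in place of its log2 850, and without centring 232 positive and 36 negative.

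The 0 pmol arrays, with the same RNA in both channels, show which features had a ratio of their own. Positive means were led by the feature at spot 16516 (1.95 ± 0.71, SD, n = 6), the magnesium transporter Nipa2 (1.79 ± 0.63, SD, n = 6) and the centrosomal protein Cep97 (1.69 ± 1.65, SD, n = 6). Without centring, these means were -8.33e-05, -0.16 and -0.26. Negative means were led by the features at spots 6250 (-2.25, n = 4) and 8549 (-2.11, n = 5) and by Palld, the actin-associated palladin (-2.18 ± 1.05, SD, n = 6). Of the 7920 features, 1993 lay off 0, 792 positive and 1201 negative, with a median absolute mean of 0.69, and 353 had an absolute mean of at least 1. Without centring 0 were positive and 7900 negative, and without 0 pmol replicate 5 or 6 the count was 1271 or 1303. It was 1006 over features measured on all 51 arrays and 713 with replicates 1 to 3. Of the 200 candidates, 12 were among the 1993. The test took its spread from all 51 arrays, and candidates tend to vary more between spiked arrays. Their separation had an SD of 0.03 at 0 pmol and between 0.17 and 1.04 at the spiked amounts. This lowers the power for candidates, so the 12 does not show that they lacked an offset. Of the gene lists, Cd3e (-1.63 ± 0.65, SD, n = 5), the mitotic kinase Aurka (1.03 ± 0.25, SD, n = 6) and Plk1 (0.90 ± 0.28, SD, n = 6) had the largest means. Their lists, T cells, NK cells and myeloid cells with 1 of 6 probes called and cell cycle with 3 of 11, did not pass the camera test. Adjusted over the list alone, a further cell cycle probe passed, with a negative mean. The cell cycle list had a negative median (-0.06) with a positive mean (0.14) and camera direction, and the tissue markers a positive median (0.10) and direction with a negative mean (-0.07). Called probes in the other lists numbered 3 of 4 for ribosomal proteins, 1 of 7 for ER folding, 3 of 13 for glycolysis, 6 of 17 for the tissue markers and 2 of 4 for oxidative phosphorylation. In limma 0 of 3 immunoglobulin and plasma cell probes passed, with 1 at an unadjusted p under 0.05.

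The ranking of features bears on the methods named in the title. Each ranking used a fit of the amount and the 0 pmol arrays alone, not the fit of all 51 arrays behind the counts of called features. At 0.1 pmol, the 200 top ranked features held 142 candidates when ranked by the absolute mean difference, 137 by the moderated statistic and 117 by the statistic without moderation. The mean difference held the most at all 9 amounts of 0.025 to 1 pmol, from 123 at 0.025 pmol to 154 at 0.75 pmol. The moderated statistic held from 121 to 139 and the unmoderated one from 110 to 127. With 3 arrays against 3, the moderated statistic ranked more candidates than the unmoderated one in 10 of 10 comparisons. The mean difference ranked more than the moderated statistic in all of these but 0.1 pmol replicates 4 to 6, where it ranked 114 and the moderated statistic 125. The moderated and unmoderated statistics had their lowest counts at 0.75 pmol replicates 4 to 6, with 18 and 2, and the mean difference had its lowest, 101, at 0.05 pmol replicates 4 to 6. The group at 0.75 pmol includes replicate 4, the array whose paired spots agreed least (r 0.20). With 0.75 pmol replicates 1 to 3 the moderated and unmoderated statistics ranked 143 and 114. The candidates had been chosen by their mean, which favours the mean difference. With candidates chosen by the moderated statistic, which favours that statistic, the mean difference led at 3 of the 9 amounts and the moderated statistic at 6. These are counts without a test.

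**Figure D4:**
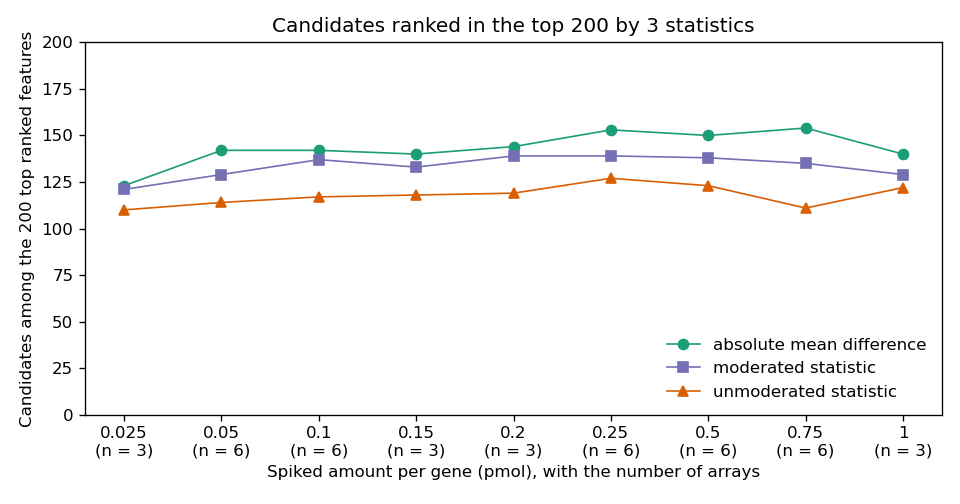
Number of the 200 candidates among the 200 top ranked features (vertical axis, 0 to 200) at each spiked amount in pmol, ranked by absolute mean difference (green circles), moderated statistic (purple squares) or unmoderated statistic (orange triangles) against 0 pmol. At 0.75 pmol the counts are 154, 135 and 111.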

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

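Tests for the array sets, the print blocks and the ceiling of the ratio were chosen after the results they bear on had been seen; the others were written before. An array far from the others was looked for in 32 groups of values, 6 of the candidate separation and the others of named features on the same arrays. It was found in 6 of the 32, where chance gives about 1 in 20 for independent values, which these are not. The array 0.75 pmol replicate 4 accounted for 5 of the 6. Its candidate separation was 0.81, against 2.72 to 3.63 on the other 5 arrays. On the same array Galnt13 had a log2 ratio of 4.71 (others 7.91 to 8.59), Tlr1 4.18 (7.12 to 7.88), Zfp330 -1.71 (-6.62 to -5.25) and the Fem1c probe at spot 2642 -1.36 (-6.34 to -5.91). At 0.5 pmol, Zfp330 on replicate 4 was -3.90, against -6.55 to -5.82 on the others.

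More features were called than were spiked, with 1042 calls outside the candidates at 2 pmol. Such calls also arose within set A, as the Ward clusterings draw it. There, 0.1 pmol replicates 4 to 6 called 486 features outside the candidates against the 0 pmol arrays of their own set. Against those of the other set they called 253. At 0.75 pmol, replicates 1 to 3 called 448 and 278, so the lower ratio of other set to same set was 0.521. That ratio cannot weigh the array sets as the cause, because the 0 pmol arrays of the 2 sets also differed in spread. The robust SD over spots, from the median absolute deviation, was 0.68 to 0.74 in 0 pmol replicates 4 to 6. It was 0.38 to 0.48 in replicates 1 to 3. Part of the calls may still come from the sets: 0 pmol replicates 4 to 6 against 1 to 3, with no spike in either, called 470 features, and with set as a covariate the calls outside the candidates at 2 pmol fell to 229, as their median size went from 1.27 to 0.97 and their median standard error from 0.34 to 0.47. They rose from 337 to 896 at 0.1 pmol under the same covariate, and to 1278 at 2 pmol with the average-linkage sets, so the share owed to the sets is not settled by these fits. Centring each print block left 118% of the main count at 2 pmol, which argues against a shift common to a whole block. Only 4.13% of these calls lay next to a candidate in the printed row, against 4.80% after shuffling, which argues against an effect of neighbours in the row. For these calls, spots above and below a candidate were not examined. The candidates themselves lay in runs down columns of some print blocks, such as the positive ones from spot 9159 to spot 9467 of block 27. Other effects of position thus stay open. Differences between hybridisations within a set stay open too. As both channels held the same RNA, no biological explanation was tested.

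The separation rose by 0.24 per doubling, where a ratio proportional to the amount would rise by 1. Each technical explanation tested left the upper 95% bound below 1: 0.602 with array set as a term, 0.542 over 0.025 to 0.25 pmol, where a ceiling at high amounts would not act, and 0.336 over the 21 arrays whose paired spots agreed best. These bounds take the arrays of 1 amount as independent and may be too low. A ceiling that already acts at the lowest amount, or compression in the authors' processing, may remain and was not tested; scaling of the arrays to one spread gave 0.19, which no longer passed (permutation p = 0.11).

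The ranking by mean difference held the most candidates at all 9 amounts, and the candidates had been chosen by their mean. With candidates chosen by the moderated statistic, of which 150 were shared, the mean difference led at 3 amounts, but that choice favours the moderated statistic in turn, so whether the lead comes from the choice is not decided. Over features measured on all 51 arrays the mean difference led at 5 of the 9, the moderated statistic led at 3 and they tied at 0.1 pmol (136 each). The rule set beforehand counted a lead at 5 or more against missing values as the cause, and 5 just meets it. The counts carry no spread and the amounts share the 0 pmol arrays. Missing values are therefore left open as well, a stricter reading than that rule. The moderated statistic ranked more candidates than the unmoderated one at 9 of 9 amounts in both settings.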

How the results depend on the processing

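The alternatives with array sets, however clustered, print blocks, single spots, control positions, capped values and doubted arrays were chosen after seeing the data. Robust moderation, the fit with only the dose and 0 pmol groups, control positions kept, capped values kept, each print block centred, and the fit without 0.75 pmol replicate 4 and the 1 pmol arrays left each count they were run on within 1.5 times; those of them run on the slope of the separation, which the first 2 do not enter, kept its side of the threshold. Replicate numbers do not pair the arrays (8 of 45 pairs correlated over 0.1, and 5 arrays correlated best with their own number); with the number as a block the counts from 0.025 to 2 pmol were 304, 329, 507, 784, 647, 1048, 2022, 632, 2450 and 1051, and it moved none by over 1.5 times. No array had its sign turned, so that alternative gave no value. Except where a sentence gives one, the cause of a move was not tested. Without centring, the counts from 0.025 to 2 pmol were 136, 143, 211, 390, 181, 488, 7231, 170, 571 and 2863, with 7900 off 0 at 0 pmol and 268 slopes, where the array medians enter each ratio; the means of spot 16516, Nipa2 and Cep97 at 0 pmol turned to -8.33e-05, -0.16 and -0.26. With arrays scaled to one spread, the count was 74 at 0.025 pmol, 186 at 0.05 and 1300 at 1 pmol, and the slope 0.19 (permutation p = 0.11). With fewer features tested, those on all 51 arrays, the counts were 190 at 0.025 pmol, 319 at 0.1, 1155 at 0.5, 1623 at 1, 1006 off 0 and 1158 slopes. At adjusted p under 0.01 they were 206, 199, 283, 374, 350, 560, 1114 and 340 from 0.025 to 0.75 pmol, 783 at 2 pmol, 1072 off 0 and 876 slopes. With an absolute change of at least 1 added, they were 640 at 0.25 pmol, 1140 at 0.5 and 353 off 0. Against 0 in place of the 0 pmol arrays, 1843 were called at 0.025 pmol, 2167 at 0.05 and 1067 at 0.75. With replicates 1 to 3, the counts were 698 at 0.025 pmol, 684 at 0.25, 963 at 0.5 and 713 off 0; with replicates 4 to 6, 1003 at 0.05 pmol, 272 at 0.1 and 967 at 0.75. With array set as a covariate, they were 48 at 0.025 pmol, 137 at 0.05, 1042 at 0.1, 358 at 0.15, 359 at 0.2, 659 at 0.5, 1480 at 1 (linked to the other sets by 0.75 pmol replicate 4 alone) and 418 at 2. Within the set of 0 pmol replicates 4 to 6, they were 810 at 0.1 and 620 at 0.25. With Ward clusterings of 4, 5, 6 and 7 sets as the covariate, they were 777, 839, 983 and 1096 at 0.1 pmol, 1101, 702, 626 and 708 at 0.5, 416, 370, 414 and 471 at 2, and 1069, 690, 517 and 183 slopes (183 with the 8 sets); with average linkage and 6 sets each of the 9 counts that could be fitted stayed within 1.5 times (1477 at 2 pmol), as did the 1744 slopes. Each spot as its own feature gave 634, 613, 891, 1302, 1140, 1699, 3278, 1062, 4042 and 2104 from 0.025 to 2 pmol, 3141 off 0 and 3073 slopes. Slopes on the amount in pmol numbered 850, and without the 0.025 pmol arrays 970. Leaving out 1 array gave 204 to 443 at 0.025 pmol, 257 to 338 at 0.05, 321 to 582 at 0.1, 381 to 865 at 0.15, 359 to 802 at 0.2, 719 to 1137 at 0.25, 1650 to 2066 at 0.5, 463 to 636 at 0.75, 1739 to 2617 at 1, 763 to 1295 at 2 and 1271 to 2020 off 0. The slope of the separation was 0.14 without the 1 pmol arrays (permutation p = 0.0785) and 0.0166 within set C (exact permutation p = 0.927), and in the alternatives other than these and the scaling it lay between 0.17 and 0.42 and kept its side of the threshold. Candidates chosen by size alone, 425 positive and 316 negative, gave 471 called at 0.5 pmol, since more were chosen. Of 1726 values of named genes under the alternatives, 1716 kept their direction and their side of the threshold, 7 lost the threshold, 4 of them the slope of Tcra with array sets, and 3 turned. Signal over background was not analysed here.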

Other observations

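The tests of the print blocks, of the signs of several probes of 1 gene, of the order of the amounts and of divisions outside the candidates were chosen after the results had been seen. Among the candidates, 3 genes had several candidate probes. Both probes of Fem1c were negative, with mean log2 ratios at 2 pmol of -7.49 and -6.93, while Hk2 had probes at 4.40 and -3.09 that carry the same sequence accession, and Cald1 had probes at 7.28 and -3.14. With signs dealt at random, as few genes of opposite sign occurred in a share of 0.87 of 10000 draws, so these 3 genes do not tell whether probes of one gene were spiked together.

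The candidates were not spread evenly over the array. Print block 27 held 14 of the 100 positive candidates, where an even spread gives 2.08, and the fullest block in 10000 draws of 100 features held 11 (permutation p = 1e-04, the smallest these draws can give). The block included Cpsf6, Tlr1, Ino80 and Polh, and the 3 steepest positive slopes all lay in it. For the negative candidates, block 38 held 9 (permutation p = 0.0116). In block 27, the positive candidates at spots 9159, 9203, 9247, 9291, 9335, 9379, 9423 and 9467 lay one below another in a single column. Negative candidates did so at spots 12498, 12542, 12586 and 12630 of block 36, and at 13116, 13160, 13204 and 13248 of block 38. Whether the gathering comes from the choice of spiked genes or from an effect of position was not tested. Some candidates may therefore not be spiked genes.

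The capped value was spread unevenly: 0 pmol replicates 4 to 6 had between 138 and 151 capped spots each, and replicates 1 to 3 between 2 and 7. Among the 11 control positions, unnamed position 110 had the smallest p, with a median log2 ratio of 0.20 ± 0.38 (SD, n = 6) at 0 pmol and -1.11 ± 1.04 (SD, n = 45) on the spiked arrays (permutation p = 0.00838, adjusted p 0.0671). The unnamed position 309 had a median log2 ratio of 5.56 ± 1.26 (SD, n = 6) at 0 pmol and 3.27 ± 2.12 (SD, n = 45) on the spiked arrays (permutation p = 0.0122, adjusted p 0.0671 over 11 positions), so a difference was not established at either.

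For the counts of called features, other divisions of the same arrays into groups of the same sizes were counted, 84 in all for 3 arrays against 6, and 100 drawn for 6 against 6. In each comparison 1 division, the real one, gave as many, but only it parts the spiked genes fully, which favours it. The highest of the others was 188 (real 394) at 0.025 pmol, 157 (329) at 0.05, 363 (496) at 0.1, 641 (845) at 0.15, 668 (704) at 0.2, 533 (1031) at 0.25, 915 (1987) at 0.5, 321 (593) at 0.75, 1490 (2562) at 1 and 774 (1239) at 2 pmol. At 0.025, 0.15, 0.2, 1 and 2 pmol, that highest division set 0 pmol replicates 4 to 6 against the rest and so followed the array sets. Calls outside the candidates were therefore counted as well. The divisions with as many, the real one included, then numbered 2 at 0.1 and 0.2 pmol and 1 at the other amounts, with 337 (highest other 350) and 543 (646) at those 2. With p adjusted over these features alone, some other division called more at 0.025 pmol (real 183, highest other 186), 0.05 (103 and 158), 0.1 (276 and 350), 0.15 (581 and 611) and 0.2 pmol (440 and 644). From 0.25 to 2 pmol the real division called the most, with 772 (271), 1742 (668), 321 (90), 2359 (1369) and 963 (623). Divisions with as many made up under 5% at every amount. As the arrays fall into sets, they cannot be exchanged freely, and spiked genes outside the candidates would still favour the real division. These shares therefore do not exclude chance. At 0.025, 0.15 and 0.2 pmol the division that follows the array sets called more features outside the candidates than the real one, where p was adjusted over those features alone. For the candidates called at 0.5 pmol and those ranked at 0.1 pmol the highest others were 149 (real 194) and 103 (137). For the slopes the amounts were reordered over whole groups, so that arrays of one amount stayed together: of 100 orders, 1, the real one, gave as many, and the highest other gave 1781 (real 1833). With array set as a term 183 slopes passed, and with the average-linkage sets 1744, so the share of these slopes owed to the sets is not settled.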
